A study of Mus musculus with 16 samples.

How the data were processed

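RNA of 16 samples of dissected, snap-frozen mucosa or tumour from mouse colon and small intestine was measured on Illumina mouse bead arrays, 1 per sample, after TRIZOL extraction and labelling to biotin cRNA (Ambion MessageAmp). Per the labels, the mice were of mixed strain and on doxycycline from 6-7 weeks, with the genotypes wt, Apcmin/+, iLIN28B (an inducible LIN28B) and iLIN28B with Apcmin/+. The number that opens each title is shared by samples that may come from 1 animal. The deposited intensity values were the average bead signal of each probe as scanned, neither background subtracted nor normalised between arrays by the authors. The deposited detection p-value of each probe and array was made by the authors against negative control beads, by software not stated. The deposited series matrix, also in intensity units, held linear transforms of those signals by a method not stated, and was used as an alternative only. Of 25697 probes, 23978 named 1 gene symbol and 1719 none, and 2 lines without a probe identifier were left out.

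The depth of an array is its signal over background: 48.3% to 56.5% of probes had a detection p under 0.05 on 14 arrays, and 12% and 5.28% on LIN28B/Apcmin colon replicate 4 and wt small intestinal replicate 1. On these 2, 79.0% and 91.9% of the 3518 bright probes (signal of at least 300 on 12 intact arrays) read under 25, and the Spearman correlation with the other arrays was -0.053 and 0.131, against 0.717 to 0.919. LIN28B/Apcmin colon replicate 3 had lost 1985 values in the same way. The fit planned before the data were examined, with its comparisons, lists, named genes and alternatives, took all 16 arrays. After the signals were seen and before any group was compared, a fit was added that leaves out arrays with under 20% of probes detected and sets signals under 25 to missing. The values of the comparisons come from this fit. The number of arrays limits the precision.

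Background was corrected by normexp from detection p-values (limma nec, offset 16), followed by log2 and quantile normalisation. Probes detected (p under 0.05) on at least 2 arrays and naming 1 gene were kept, with the probe of highest mean for each gene, which gave 11370 genes on 16 arrays and 11230 on 14. Means of 7 groups were fitted with lmFit and eBayes, with the title number as a random block (duplicateCorrelation, consensus 0.625 on 16 arrays and -0.0643 on 14, with 9 and 7 residual degrees of freedom). On the 14 arrays, the numbers 2135 and 1737 each cover every array of a group, and 1032 joins a wt colon array to the lone wt small intestinal one. The block therefore cannot measure spread between animals in those groups. With a negative consensus, their standard errors and p-values may be too small if a number stands for an animal. Each of 12 comparisons was a contrast tested two-sided, with Benjamini-Hochberg adjusted p under 0.05 within the comparison. A comparison of both organs was the mean of the colon and the small intestinal contrast, and the interaction their difference. Versions were R 4.3.3, limma 3.58.1, version 1.17.8 of data.table, Python 3.11 and matplotlib 3.10.9. Simulated arrays were drawn with the gene means and residual spreads of each fit and all groups alike, except for 100 genes changed 2-fold and 100 changed 4-fold. On 14 arrays 13% to 78% of the 2-fold and 65% to 93% of the 4-fold changes were recovered. The fit over 16 arrays recovered 0% at 2-fold and 0% to 12% at 4-fold.

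Gene lists written before the data were examined were tested with cameraPR (preset correlation 0.01, adjusted over lists within a comparison), again with an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance. A member was matched by its symbol, or by a former name that is not the symbol of another gene, a condition set after the results were seen, since a former name had put Nckap1, Pigq and Eno1b on lists. The 31 lists were B and plasma cell, MHC class II, Notch and secretory fate, Paneth cell, T cell, Wnt target, adipocyte, colonocyte, endothelial, enteroendocrine, exocrine pancreas, fetal and regenerating epithelium, fibroblast and matrix, gastric and Brunner gland, glycolysis, goblet cell, immediate early and heat shock, imprinted growth, interferon response, intestinal stem cell, invasion and mesenchymal transition, let-7 target, myeloid, oxidative phosphorylation, proliferation, red blood cell, regenerating islet-derived and antimicrobial, ribosome biogenesis, small intestinal enterocyte, smooth muscle and tuft cell genes. Named genes were chosen by a rule of the same time: the 6 largest rises and falls of a main comparison (3 of a secondary one) among called genes whose groups do not overlap (for both organs in either organ, none for the interaction), skipping unnamed models. With fewer than 3 called in a direction, the 3 of smallest p are given as not passed. The rule adds members of the lists and genes fixed beforehand, such as Igf2bp1. Probes for Lin28b, Igf2bp2 and H19 were not analysed here. Alternatives changed the background correction, normalisation, deposited values, detection filter, probe rule, block, arrays in the fit, variance model, array weights, threshold, and left out each array and title number. Splits of the samples within organ were counted for the comparison of both organs, the only comparison with at least 3 arrays on each side.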

Results

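Gene expression was measured on Illumina mouse bead arrays, 1 array per sample, in 16 samples of snap-frozen mucosa or tumour from the colon and small intestine of mice of a mixed strain given doxycycline. The design crossed an Apcmin allele, which truncates Apc, the protein that holds back Wnt signalling, with an inducible LIN28B, an RNA-binding protein that blocks the maturation of let-7 microRNAs. The colon groups were wt mucosa (n = 2), Apcmin tumours (n = 2) and LIN28B/Apcmin tumours (n = 4). The small intestinal groups were wt mucosa (n = 2), LIN28B tumours (n = 2), Apcmin tumours (n = 2) and LIN28B/Apcmin tumours (n = 2). The LIN28B small intestinal tumours came from mice of 8 months, with a histology of adenoma or adenocarcinoma, and every other sample from mice of 3 months. The titles gave D for every small intestinal sample except LIN28B replicate 2, titled Jej. Between 48.3% and 56.5% of the 25697 probes were detected on 14 arrays, with a median signal from 51 to 79.9. The other 2 arrays carried almost no signal: 12% of probes were detected on LIN28B/Apcmin colon replicate 4 and 5.28% on wt small intestinal replicate 1, with median signals of 12 and 11.4. The values given come from the 14 readable arrays, a choice made after the signal of each array was seen and before any group comparison. The count of the fit planned over all 16 stands beside each. This leaves 1 wt small intestinal sample, assumed to vary like the other groups, so that tests against it miss variation between wt animals. It also leaves 3 LIN28B/Apcmin colon tumours. These 3 share 1 title number, as do both LIN28B small intestinal tumours, so that, if a number stands for an animal, genotype and animal cannot be told apart there. The number of arrays limits the precision of every value.

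**Figure D1:**
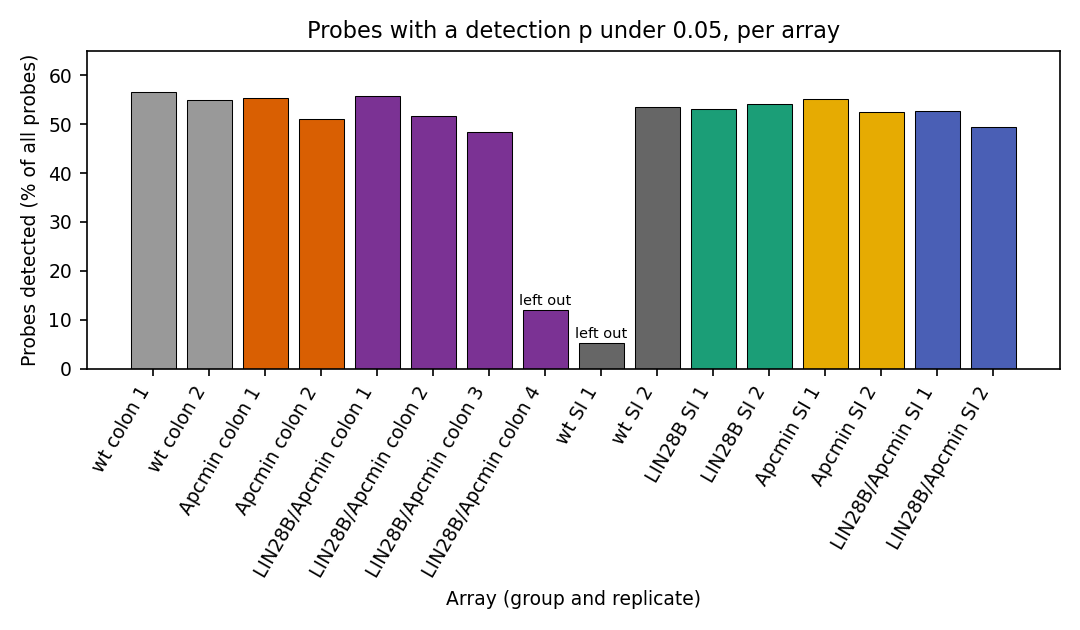
Percent of probes detected (detection p under 0.05) on each of the 16 arrays, by group, with the 2 arrays left out of the 14 marked. The 14 arrays kept lie between 48.3% and 56.5%, the 2 others at 12% and 5.28%.

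Each change is a log2 difference of group means ± its limma standard error, p-values are adjusted over all genes tested in the comparison, and counts of a gene list are of its measured members. Where a gene was undetected on every readable array of a group, a bound is given as a fold. It sets the mean of the detected group against the other group with each array raised to its lowest detected value where it lay lower. Igf2bp1, an RNA-binding protein and let-7 target (probe ILMN_3006804), was detected on 2 of the 3 LIN28B/Apcmin colon arrays, its signal on replicate 3 being lost, and on all LIN28B (2 of 2) and LIN28B/Apcmin (2 of 2) small intestinal arrays. It was detected on 0 of the 7 arrays of the groups without LIN28B. Igf2bp3, a paralog, had 2 probes. ILMN_1218913, which gave its values, was detected on 3 of 3 LIN28B/Apcmin colon and 2 of 2 LIN28B/Apcmin small intestinal arrays, and on 1 array each of wt colon, wt small intestine and Apcmin small intestine. ILMN_1226175 was detected on 2 of 3 and 2 of 2 of the LIN28B/Apcmin arrays and on no other. Across both organs, Igf2bp1 and Igf2bp3 passed as higher in LIN28B/Apcmin than in Apcmin tumours (adjusted p from 0.00902 to 0.0166), without a size, since Igf2bp1 was undetected in both Apcmin groups and Igf2bp3 in Apcmin colon tumours. In the small intestine Igf2bp1 was at least 7.98-fold higher. Lin28a, the paralog of LIN28B, and Hmga2, a chromatin protein and let-7 target, were not detected on any of the 14 arrays. Apc differed by 0.057 ± 0.19, Myc by 0.24 ± 0.18 and Igf2, the fetal growth factor, by -0.35 ± 0.33 in the same comparison (adjusted p = 0.886, 0.448 and 0.560), none of them past the threshold. Lin28b, Igf2bp2 and H19 were not analysed here.

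**Figure D2:**
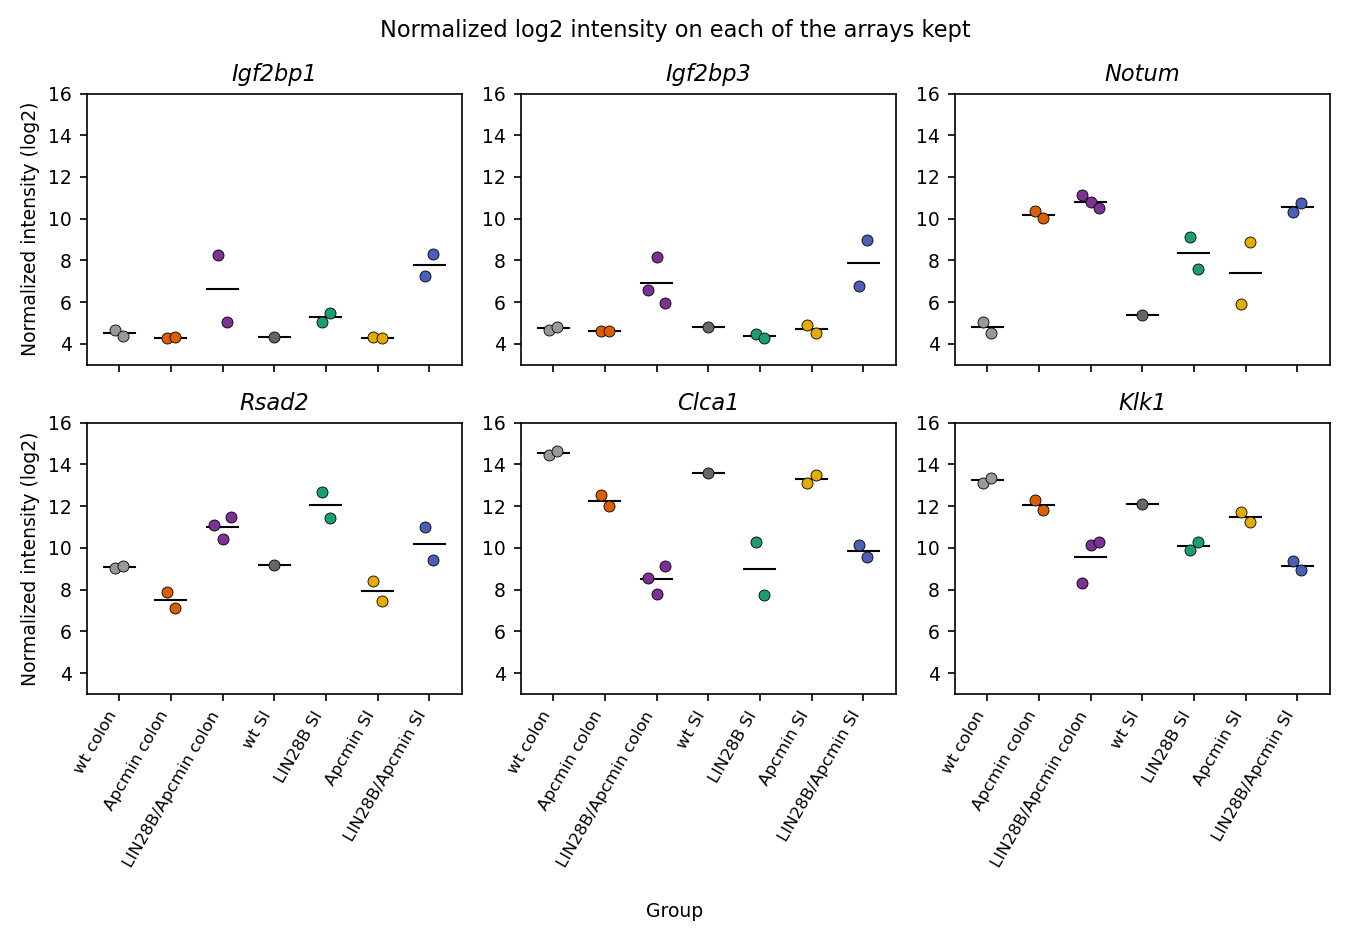
Normalised log2 intensity of 6 genes on each of the 14 arrays, by group, with bars at the group means. Igf2bp1 and Igf2bp3 stand above the groups without LIN28B in most LIN28B/Apcmin samples, and Clca1 and Klk1 lie lower in LIN28B/Apcmin than in Apcmin tumours of both organs.

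The first comparison asks what separates Apcmin colon tumours (n = 2) from wt colon mucosa (n = 2). Wnt target genes rose: 13 of 23 rose and 1 fell (17 and 1 adjusted over the list alone, camera adjusted p = 8.47e-12). Notum, a secreted Wnt inhibitor, was 42.5-fold higher (5.41 ± 0.76), and the transcription factors Prox1 (5.02 ± 0.77) and Sp5 (4.54 ± 0.37), the Wnt antagonist Wif1 (4.94 ± 0.75), the feedback gene Axin2 (2.47 ± 0.21) and the stem cell receptor Lgr5 (3.44 ± 0.51) rose with it (adjusted p from 7.52e-05 to 0.00183). Of the intestinal stem cell genes, 6 of 19 rose and 2 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.000667). They included the RNA-binding protein Mex3a (2.77 ± 0.28), which rose. Colonocyte genes fell: 16 of 23 fell and 0 rose (21 and 0 adjusted over the list alone, camera adjusted p = 1.24e-23). Cyp2c55, a cytochrome P450, was 85.7-fold lower (-6.42 ± 0.86), and the water channel Aqp8 (-4.09 ± 0.39) and the carbonic anhydrase Car4 (-3.56 ± 0.98) fell too (adjusted p from 0.000121 to 0.0337). Slc51a, a subunit of the bile acid transporter, was at least 55.8-fold lower. Among the other largest falls were the cytochrome P450 Cyp2c65 (at least 40.7-fold lower), the retinaldehyde dehydrogenase Aldh1a1 (at least 28.2-fold lower), the carboxylesterase Ces1f (-4.93 ± 0.69) and the dipeptidase Dpep1 (-4.83 ± 0.68).

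Secretory lineages moved apart. Of the goblet cell genes, 5 of 16 fell and 0 rose (5 and 1 adjusted over the list alone, camera adjusted p = 0.00432). Members included the secreted Clca1 (-2.30 ± 0.65) and Retnlb (-4.21 ± 1.22) and the transcription factor Spdef (-1.44 ± 0.39). Of the enteroendocrine genes, 1 of 22 rose and 9 fell (1 and 13 adjusted over the list alone, camera adjusted p = 7.72e-07). The hormones secretin (Sct, -4.14 ± 0.45), somatostatin (Sst, -3.68 ± 0.51) and proglucagon (Gcg, -3.68 ± 0.49) fell. Paneth cell genes rose: 5 of 10 rose and 0 fell (5 and 1 adjusted over the list alone, camera adjusted p = 3.25e-05). These included the defensin Defa20 (7.87 ± 0.55), read by a probe with near-identical paralogs not tested for cross-reaction, the lysozyme Lyz1 (2.26 ± 0.31) and the matrix metalloproteinase Mmp7, at least 6.49-fold higher. Myeloid genes rose: 11 of 22 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 2.38e-09). They included S100a8 (6.39 ± 0.62) and S100a9 (5.36 ± 0.59), calcium-binding proteins of neutrophils, the cytokine Il1b (4.89 ± 0.41) and the chemokine Cxcl2, at least 6.23-fold higher. Red blood cell genes, which follow how much blood a sample holds, rose beside them: 3 of 5 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0199, adjusted p = 0.399 with an estimated correlation). Alas2, a heme synthesis enzyme, read 4.88 and 4.50 log2 intensity in wt and 7.24 and 6.71 in Apcmin samples. Of the invasion and mesenchymal transition genes, 11 of 22 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 4.71e-08). They included the matrix metalloproteinases Mmp10 (6.22 ± 0.51), Mmp13 (5.29 ± 0.48) and Mmp9 (2.89 ± 0.43). Of the fetal and regenerating epithelium genes, 5 of 12 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 1.28e-05, adjusted p = 0.0650 with an estimated correlation). Those called included the chaperone clusterin (Clu, 4.15 ± 0.28). The lipoxygenase Alox12 (5.76 ± 0.66), the secreted WAP-domain protein Wfdc18 (5.48 ± 0.40), the siderophore-binding Lcn2 (5.41 ± 0.81) and the lipase-related Pnliprp1 (5.51 ± 1.08) also rose.

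Smooth muscle markers, which follow how much muscle wall a sample holds, moved with these groups: 14 of 17 fell and 0 rose (16 and 0 adjusted over the list alone, camera adjusted p = 1.70e-20). Among them were desmin (Des) at -3.58 ± 0.48 and transgelin (Tagln) at -3.57 ± 0.39. Of the proliferation genes, 6 of 27 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 5.08e-05, adjusted p = 0.458 with an estimated correlation). They included the replication helicase subunits Mcm7 (1.57 ± 0.37) and Mcm4 (1.38 ± 0.24). Of the oxidative phosphorylation genes, 6 of 26 fell and 0 rose (12 and 0 adjusted over the list alone, camera adjusted p = 1.27e-05). Of the interferon response genes, 3 of 22 fell and 0 rose (3 and 0 adjusted over the list alone, camera adjusted p = 0.0120, adjusted p = 0.515 with an estimated correlation). The transcription factor Irf7 (-2.33 ± 0.43) was among those that fell. Limma called 1708 of the 11230 genes on the 14 arrays, 782 higher and 926 lower. Over all 16 arrays, as planned, limma called 0, with 262 genes at an unadjusted p under 0.05. Leaving out 1 array or title number moved the count from 573 without wt colon replicate 1 to 2162 without Apcmin small intestinal replicate 1, over 1.5 times off in 5 of 17 runs. Over all 16 arrays, 0 of 41 called genes named kept their call and 41 their direction, as both groups were unchanged.

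What LIN28B adds in the colon was read from LIN28B/Apcmin (n = 3) against Apcmin colon tumours (n = 2). Interferon response genes rose: 11 of 22 rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 1.53e-22). Rsad2 (viperin), an antiviral enzyme, was 11.3-fold higher (3.50 ± 0.51), and the interferon-induced Oas2 (3.37 ± 0.64), Ifit2 (2.91 ± 0.60) and Ifit3 (2.88 ± 0.45) rose with it (adjusted p from 0.0120 to 0.0397). Goblet cell genes fell: 7 of 16 fell and 0 rose (11 and 0 adjusted over the list alone, camera adjusted p = 8.24e-17). The secreted Clca1 was 13.6-fold lower (-3.77 ± 0.58), and Klk1 (-2.47 ± 0.45), a tissue kallikrein, Rep15 (-2.27 ± 0.30), a regulator of vesicle recycling, and Zg16 (-1.76 ± 0.20), a lectin of the mucus, fell too (adjusted p from 0.00416 to 0.0258). Of the colonocyte genes, 4 of 23 fell and 0 rose (7 and 0 adjusted over the list alone, camera adjusted p = 3.96e-12). Among them were the mucosal pentraxin Mptx1 (-4.39 ± 0.24), the transglutaminase Tgm3 (-2.44 ± 0.18), the water channel Aqp8 (-2.33 ± 0.34) and the acute phase protein Saa1 (-1.57 ± 0.29). Of the exocrine pancreas genes, 3 of 8 fell and 0 rose (4 and 0 adjusted over the list alone, camera adjusted p = 6.71e-07). They included Sycn (-4.55 ± 0.44), of zymogen granules, colipase (Clps, -2.49 ± 0.44) and the elastase Cela1 (-1.61 ± 0.35). Of the enteroendocrine genes, 2 of 22 fell and 0 rose (4 and 0 adjusted over the list alone, camera adjusted p = 0.000296, adjusted p = 0.213 with an estimated correlation). Members included the colonic hormone Insl5 (-3.35 ± 0.47) and Resp18, at least 2.44-fold lower. The actin-severing Scin (-3.17 ± 0.38) and the caspase Casp14 (-3.69 ± 0.31) were among the largest falls, and the apolipoprotein Apoc4 (3.58 ± 0.59) and Apol9b, at least 8.41-fold higher, among the largest rises.

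Targets of let-7, the microRNA that LIN28B blocks, rose as a group: 3 of 28 rose and 0 fell (11 and 1 adjusted over the list alone, camera adjusted p = 4.99e-06). The ubiquitin-conjugating enzyme Cdc34 (1.07 ± 0.23) and the transcription regulators Arid3b (1.07 ± 0.20) and E2f6 (1.00 ± 0.19) passed (adjusted p from 0.0258 to 0.0495). Igf2bp1 (at least 3.55-fold higher, adjusted p = 0.163) and Igf2bp3 (at least 4.25-fold higher, adjusted p = 0.0912) did not. Of the Wnt target genes, 0 of 23 rose and 0 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.0629). Axin2 stood at 0.52 ± 0.19 and Lgr5 at -1.89 ± 0.45, neither past the threshold. In the fetal and regenerating epithelium list, 2 of 12 fell and 0 rose (2 and 1 adjusted over the list alone, camera adjusted p = 0.0695). These included clusterin (Clu, -1.48 ± 0.25) and the matricellular protein Ccn2 (-1.16 ± 0.22). Smooth muscle markers were lower as well: 2 of 17 fell and 0 rose (4 and 0 adjusted over the list alone, camera adjusted p = 3.38e-05, adjusted p = 0.268 with an estimated correlation). Actg2 (-1.75 ± 0.38) and the actinin-binding Pdlim3 (-1.49 ± 0.22) fell. Limma called 187 of the 11230 genes on the 14 arrays, 80 higher and 107 lower, where median scaling gave 76 and 300. The limma fit planned over all 16 arrays called 0, with 200 genes at an unadjusted p under 0.05. The count with an array or title number left out ran from 5 without Apcmin colon replicate 2 to 479 without LIN28B/Apcmin colon replicate 1, over 1.5 times off in 14 of 16 runs. Averaging the arrays that share a title number left 27. Of the 28 called genes named here, 4 kept their call whichever array was left out and 26 kept their direction over all 16 arrays, where Cdc34 and E2f6 turned.

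The same question in the small intestine set LIN28B/Apcmin (n = 2) against Apcmin tumours (n = 2). Paneth cell genes fell: 4 of 10 fell and 0 rose (6 and 0 adjusted over the list alone, camera adjusted p = 5.03e-06). The antimicrobial Ang4 was 56.4-fold lower (-5.82 ± 0.94). The intelectin Itln1 (-3.34 ± 0.38) and the unlisted defensin Defa39 (-5.79 ± 0.43) fell with it (adjusted p from 0.000143 to 0.0111). Of the enteroendocrine genes, 7 of 22 fell and 0 rose (13 and 0 adjusted over the list alone, camera adjusted p = 3.63e-08). The hormones peptide YY (Pyy, -3.74 ± 0.96), Sst (-2.69 ± 0.51) and Gip (-1.90 ± 0.21) fell and Gcg was at least 4.94-fold lower. Tuft cell genes fell: 5 of 12 fell and 0 rose (5 and 0 adjusted over the list alone, camera adjusted p = 8.35e-05). Those called included the leukotriene synthesis protein Alox5ap (-2.51 ± 0.24), the cation channel Trpm5 (-2.15 ± 0.42) and the kinase Dclk1 (-1.61 ± 0.34). Goblet cell genes fell: 3 of 16 fell and 0 rose (8 and 0 adjusted over the list alone, camera adjusted p = 0.000127). Among them were Clca1 (-3.45 ± 0.65), Klk1 (-2.35 ± 0.51) and the transcription factor Creb3l1 (-1.27 ± 0.33), the last -0.69 (adjusted p = 0.211) without Apcmin replicate 1. The nucleoside transporter Slc28a1 (-4.20 ± 0.45), the tryptophan-degrading Ido1 (-4.11 ± 0.66), the aquaglyceroporin Aqp7 (-4.07 ± 0.35), the carbonic anhydrase Car4 (-3.89 ± 0.98) and the stem cell marker Olfm4 (-2.73 ± 0.69) also fell (adjusted p from 0.000481 to 0.0479). Without Apcmin replicate 2, Car4 was -1.84 (adjusted p = 0.0498) and Trpm5 -1.40 (adjusted p = 0.0230). Without LIN28B/Apcmin replicate 2, Olfm4 was -1.23 (adjusted p = 0.153) and Dclk1 -1.03 (adjusted p = 0.152).

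Targets of let-7 rose here too: 5 of 28 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 4.19e-05). Igf2bp1 was at least 7.98-fold higher, and Igf2bp3 (3.15 ± 0.68), Cdc34 (1.13 ± 0.26) and the transcription factor Plagl2 (0.97 ± 0.20) rose (adjusted p from 0.0249 to 0.0368). Of the Wnt target genes, 1 of 23 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.0578). The 1 that rose was Notum (3.15 ± 0.76), which without Apcmin replicate 1 was 1.66 (adjusted p = 0.124). The largest rises were in the transcription factors Sox17 (4.35 ± 0.64) and Gbx2 (3.87 ± 0.76), the glucocorticoid-induced immunophilin Fkbp5 (3.75 ± 0.35), the dicarboxylate transporter Slc13a2 (3.68 ± 0.64) and the gastric proton pump subunits Atp4a, at least 14.3-fold higher, and Atp4b, at least 10.3-fold higher. Slc13a2 was 2.44 (adjusted p = 0.0169) without Apcmin replicate 1, and Cdc34 0.71 (adjusted p = 0.227) without LIN28B/Apcmin replicate 2. Of the proliferation genes, 0 of 27 rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 1.70e-06, adjusted p = 0.449 with an estimated correlation). Of the interferon response genes, 1 of 22 rose and 0 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.766). The 1 that rose was Rsad2 (2.27 ± 0.57), which without LIN28B/Apcmin replicate 1 was 1.49 (adjusted p = 0.108). Smooth muscle markers were lower: 8 of 17 fell and 0 rose (11 and 0 adjusted over the list alone, camera adjusted p = 5.58e-09, adjusted p = 0.0621 with an estimated correlation). Desmin (Des, -2.39 ± 0.48) and Actg2 (-2.12 ± 0.43) fell. The title of LIN28B/Apcmin replicate 2 named both tumour and mucosa. Limma called 587 of the 11230 genes on the 14 arrays, 271 higher and 316 lower. Over all 16 arrays, as planned, limma called 0, with 71 genes at an unadjusted p under 0.05. The small intestine fitted alone and the 2 groups fitted alone had 12 and 0 called by limma (1569 genes at an unadjusted p under 0.05 in the latter), so that the count rests on a spread shared with the colon groups. Single leave-outs took the count from 52 without LIN28B/Apcmin small intestinal replicate 2 to 1542 without LIN28B/Apcmin small intestinal replicate 1, over 1.5 times off in 10 of 17 runs, and 9 of the 32 called genes named kept their call whichever array was left out. Without Apcmin small intestinal replicate 1, which lay near wt mucosa for Notum (5.91 against 5.40 log2 intensity), the count was 234.

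Both organs were averaged for LIN28B/Apcmin (n = 5) against Apcmin tumours (n = 4). Goblet cell genes fell: 10 of 16 fell and 0 rose (13 and 0 adjusted over the list alone, camera adjusted p = 2.44e-13). Clca1 was 12.2-fold lower (-3.61 ± 0.44), with Klk1 (-2.41 ± 0.34), the vesicle protein Sytl2 (-1.43 ± 0.28) and Rep15 (-1.66 ± 0.23) (adjusted p from 0.00217 to 0.0181). Enteroendocrine genes fell: 8 of 22 fell and 0 rose (11 and 0 adjusted over the list alone, camera adjusted p = 5.45e-10). They included Pyy (-3.32 ± 0.64). Paneth cell genes fell: 3 of 10 fell and 0 rose (7 and 1 adjusted over the list alone, camera adjusted p = 5.85e-06). Members included Ang4 (-3.37 ± 0.63), which fell more in the small intestine, and Itln1 (-2.43 ± 0.26). Tuft cell genes fell: 3 of 12 fell and 0 rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.00294). These included Alox5ap (-1.09 ± 0.17), which did not fall in colon (8.35 and 9.14 log2 intensity, Apcmin 8.43 and 8.40). Colonocyte genes fell: 5 of 23 fell and 0 rose (9 and 0 adjusted over the list alone, camera adjusted p = 5.33e-08). Those called included Car4 (-3.25 ± 0.66) and Mptx1 (-2.35 ± 0.17). The kallikrein Klk1b27 (-2.89 ± 0.39), a near-identical paralog of others on the array, was among the largest falls. Of the exocrine pancreas genes, 3 of 8 fell and 0 rose (3 and 0 adjusted over the list alone, camera adjusted p = 6.35e-05), Sycn (-2.76 ± 0.33) and Clps (-2.63 ± 0.33) among them.

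Targets of let-7 rose: 9 of 28 rose and 0 fell (14 and 1 adjusted over the list alone, camera adjusted p = 1.55e-08). Among them were Cdc34 (1.10 ± 0.18) and the transcription factor Arid3a (0.88 ± 0.20) beside Igf2bp1 and Igf2bp3 (adjusted p from 0.00712 to 0.0265). Wnt target genes rose: 5 of 23 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.00897). They included Prox1 (2.04 ± 0.52), Notum (1.89 ± 0.51), the receptor Tnfrsf19 (1.79 ± 0.44), the Wnt inhibitor Apcdd1 (1.64 ± 0.42) and Axin2 (0.61 ± 0.14) (adjusted p from 0.0318 to 0.0496). Without Apcmin small intestinal replicate 1, Prox1 was 1.23 (adjusted p = 0.0184) and Notum 1.14 (adjusted p = 0.0525). Lgr5 stood at -0.044 ± 0.34 (adjusted p = 0.954). Interferon response genes rose: 9 of 22 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 1.83e-08, adjusted p = 0.220 with an estimated correlation). Members included Rsad2 (2.89 ± 0.38) and Ifit3 (2.30 ± 0.34). The transcription factor Sox17 (3.24 ± 0.43), the homeobox gene Msx1 (3.12 ± 0.64), the apolipoprotein Apoc4 (3.35 ± 0.45), the proteoglycan Gpc3 (2.82 ± 0.58) and Bpifb1 (3.48 ± 0.86), a secreted protein of mucosal surfaces, were among the largest rises (adjusted p from 0.00314 to 0.0382). Bpifb1 was 2.16 (adjusted p = 0.0214) without Apcmin small intestinal replicate 1. The antimicrobial lectins Reg3b (2.28 ± 0.56) and Reg3g (2.17 ± 0.56) rose. Smooth muscle markers were lower, desmin (Des, -1.96 ± 0.32) among them: 9 of 17 fell and 0 rose (11 and 0 adjusted over the list alone, camera adjusted p = 1.35e-11). In both organs taken singly, 15 genes were higher and 24 lower, against 1.93 and 3.01 for independent calls, and 2 moved in opposite directions. Limma called 772 of the 11230 genes on the 14 arrays, 373 higher and 399 lower, where median scaling gave 193 and 487. Over all 16 arrays, as planned, limma called 0, with 148 genes at an unadjusted p under 0.05. With an array or title number left out the count ran from 103 without Apcmin colon replicate 2 to 1537 without Apcmin small intestinal replicate 2, over 1.5 times off in 9 of 16 runs, and 14 of the 31 called genes named kept their call whichever array was left out. The groups compared, fitted alone, had 221 called. With the arrays that share a title number averaged the count was 142. Cdc34 and Axin2 over all 16 arrays turned direction and the other 29 called genes named here did not.

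**Figure D3:**
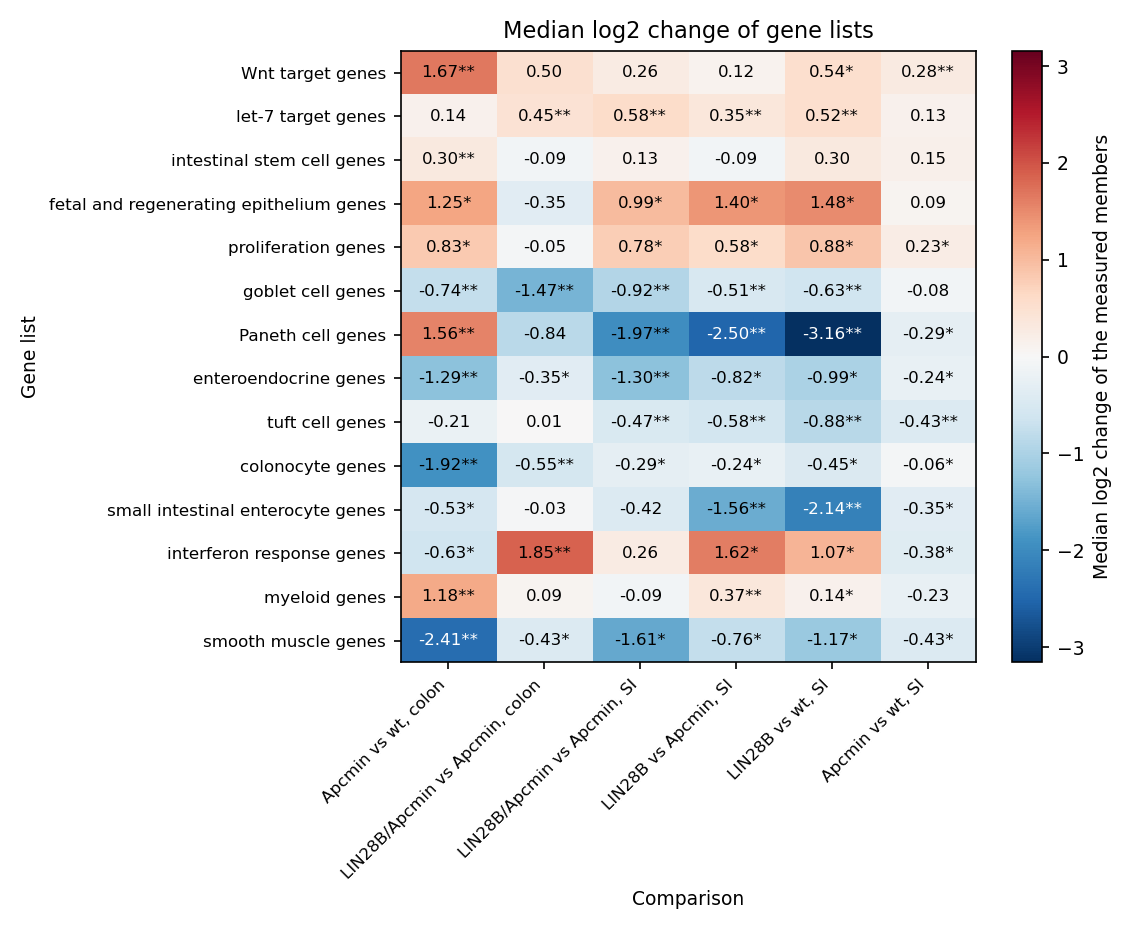
Median log2 change of 14 gene lists (vertical) in 6 comparisons (horizontal) on the 14 arrays, coloured from blue (lower) to red (higher), with * for a camera adjusted p under 0.05 and ** where it also holds with an estimated correlation. The goblet cell list is lower in LIN28B/Apcmin than in Apcmin tumours of the colon (-1.47) and small intestine (-0.92), and the interferon list is higher in the colon (1.85).

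LIN28B alone was set against Apcmin alone in small intestinal tumours (n = 2 and 2), groups that also differ in age (8 and 3 months) and, for 1 LIN28B sample, in the site titled. Interferon response genes rose: 8 of 22 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 1.55e-11, adjusted p = 0.0846 with an estimated correlation). Ifit2 was 22.0-fold higher (4.46 ± 0.66), with Rsad2 (4.11 ± 0.56), Oas2 (3.22 ± 0.64) and the chemokine Cxcl10 (3.42 ± 0.62) (adjusted p from 0.00535 to 0.0286). Of the myeloid genes, 4 of 22 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.000222). These included S100a8 (3.47 ± 0.61), S100a9 (3.27 ± 0.58) and Il1b (2.87 ± 0.40). The antimicrobial lectin Reg3g (4.10 ± 0.82), the acute phase protein Saa3 (3.80 ± 0.85), the lipid scramblase Atg9b (3.52 ± 0.78) and the heat shock proteins Hspa1a (2.61 ± 0.43) and Hsph1 (2.03 ± 0.22) rose (adjusted p from 0.00109 to 0.0372). Without Apcmin replicate 1, Saa3 was 1.95 (adjusted p = 0.0343) and Atg9b 1.79 (adjusted p = 0.0178). Paneth cell genes fell: 5 of 10 fell and 0 rose (7 and 0 adjusted over the list alone, camera adjusted p = 4.39e-09). The lipase Pnliprp2 (-4.40 ± 0.67), Ang4 (-4.17 ± 0.93) and the unlisted defensins Defa39 (114-fold, -6.83 ± 0.42) and Defa26 (-5.81 ± 0.87) fell. Small intestinal enterocyte genes fell: 8 of 28 fell and 0 rose (16 and 0 adjusted over the list alone, camera adjusted p = 3.62e-14). Those called included the cytochrome P450 Cyp3a11 (-5.05 ± 0.81), the apolipoprotein Apoc3 (-3.59 ± 0.59) and the disaccharidase Treh (-3.19 ± 0.74). Without LIN28B replicate 2 (Jej) these were -3.20 (adjusted p = 0.0110), -2.23 (adjusted p = 0.0123) and -1.64 (adjusted p = 0.286). The cytochrome P450s Cyp2c55 (-5.10 ± 0.85) and Cyp2b10 (-4.68 ± 0.69) fell, and Slc28a1 was at least 24.7-fold lower. Of the goblet cell genes, 1 of 16 fell and 0 rose (2 and 0 adjusted over the list alone, camera adjusted p = 0.0144). The 1 that fell was Clca1 (-4.28 ± 0.64).

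Targets of let-7 rose in LIN28B against Apcmin small intestinal tumours: 4 of 28 rose and 0 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.00971). Among them were Plagl2 (1.09 ± 0.20), Cdc34 (1.07 ± 0.26), E2f6 (0.88 ± 0.21) and the cyclin Ccnd1 (1.62 ± 0.39) (adjusted p from 0.0165 to 0.0493). Ccnd1 was 0.85 (adjusted p = 0.159) without Apcmin replicate 1. Of the Wnt target genes, 1 of 23 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.417). Tuft cell genes fell: 3 of 12 fell and 0 rose (5 and 1 adjusted over the list alone, camera adjusted p = 5.21e-05). They included the leukotriene synthase Ltc4s (-1.61 ± 0.23). Of the fetal and regenerating epithelium genes, 3 of 12 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 1.21e-05, adjusted p = 0.0846 with an estimated correlation). Members included Clu (1.42 ± 0.27). Both here and in LIN28B/Apcmin against Apcmin colon tumours, 24 genes were higher and 15 lower, where independent calls would share 1.20 and 2.33, and 2 (Ccn2 and Clu) moved in opposite directions. Limma called 414 of the 11230 genes on the 14 arrays, 169 higher and 245 lower, where median scaling gave 1011 and 253. With the 16 arrays of the planned fit, limma called 0, and 48 genes had an unadjusted p under 0.05. Fits of the small intestine alone and of the 2 groups alone both had 0 called by limma (1592 and 1643 genes at an unadjusted p under 0.05). Leaving out single arrays or numbers gave counts from 53 without LIN28B small intestinal replicate 2 to 1295 without Apcmin small intestinal replicate 2, over 1.5 times off in 14 of 16 runs, and 9 of the 29 called genes named kept their call whichever array was left out. Averaging arrays of 1 title number left 63, since both LIN28B arrays carry 1 number.

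LIN28B small intestinal tumours (n = 2) were also compared with wt small intestinal mucosa (n = 1), the latter titled D. Gastric and Brunner gland genes fell: 4 of 14 fell and 0 rose (4 and 0 adjusted over the list alone, camera adjusted p = 2.66e-10). These included the stomach mucin Muc5ac at least 72.3-fold lower, Gkn2 (-5.46 ± 0.67), a gastrokine, and the trefoil factor Tff1 (-3.66 ± 0.70) (adjusted p from 7.00e-06 to 0.0203). Exocrine pancreas genes fell: 4 of 8 fell and 0 rose (7 and 0 adjusted over the list alone, camera adjusted p = 4.92e-18). Those called included chymotrypsinogen (Ctrb1) at least 10.3-fold lower, Ctrl (-3.58 ± 0.31) and Clps (-4.12 ± 0.60). Adjacent tissue may add to both lists and to the epithelial values, though Sycn and Clps also read high in wt colon. Paneth cell genes fell: 5 of 10 fell and 0 rose (8 and 0 adjusted over the list alone, camera adjusted p = 2.79e-09). Pnliprp2 (-6.39 ± 0.83), Itln1 (-3.98 ± 0.47) and the unlisted Defa39 (-7.72 ± 0.52) fell. Small intestinal enterocyte genes fell: 6 of 28 fell and 0 rose (19 and 0 adjusted over the list alone, camera adjusted p = 6.93e-14). They included Cyp3a11 (-5.38 ± 0.99), the glucose transporter Slc2a2 (-4.13 ± 0.98) and the apolipoprotein Apoa4 (-3.36 ± 0.64). With the D sample alone, without LIN28B replicate 2 (Jej), they were -3.53 (adjusted p = 0.00582), -2.47 (adjusted p = 0.144) and -2.20 (adjusted p = 0.0223). Tuft cell genes fell: 4 of 12 fell and 0 rose (6 and 0 adjusted over the list alone, camera adjusted p = 3.13e-08). Members included Ltc4s (-2.77 ± 0.28) and Alox5ap (-2.53 ± 0.30). The glycosylphosphatidylinositol-anchored Psca (-6.29 ± 0.52), the mucin-like Mucl3 (-6.34 ± 1.32) and Clca1 (-4.61 ± 0.79) were among the other large falls.

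Against the same wt sample, S100a8 was at least 23.0-fold, Saa3 at least 59.8-fold, haptoglobin (Hp) at least 29.9-fold and Bpifb1 at least 138-fold higher in LIN28B tumours. The cytokine Il1b (3.65 ± 0.50), Lcn2 (4.25 ± 0.98), Ifit2 (4.91 ± 0.81), Mmp13 (2.78 ± 0.58) and Atg9b (4.97 ± 0.96) rose (adjusted p from 0.00445 to 0.0412). Of the let-7 targets, 1 of 28 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.00387). The 1 that rose was Plagl2 (1.40 ± 0.24). Of the interferon response genes, 2 of 22 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.000133, adjusted p = 0.326 with an estimated correlation). Of the proliferation genes, 1 of 27 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 7.32e-06, adjusted p = 0.326 with an estimated correlation). Of the immediate early and heat shock genes, a sign of tissue handling, 5 of 15 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.00213, adjusted p = 0.0644 with an estimated correlation). These included Hspa1a (3.03 ± 0.53) and Hsph1 (2.10 ± 0.27). Smooth muscle markers stood lower: 2 of 17 fell and 0 rose (10 and 0 adjusted over the list alone, camera adjusted p = 1.71e-06, adjusted p = 0.121 with an estimated correlation). Limma called 419 of the 11230 genes on the 14 arrays, 170 higher and 249 lower, where median scaling gave 456 and 298. Over all 16 arrays, as planned, limma called 0, with 139 genes at an unadjusted p under 0.05. Fits of the small intestine alone and of the 2 groups alone had 12 and 47 called by limma. Leave-outs of an array or number gave counts from 80 without LIN28B small intestinal replicate 2 to 1197 without LIN28B/Apcmin colon replicate 2, over 1.5 times off in 13 of 14 runs, and 18 of the 29 called genes named kept their call whichever array was left out. Title numbers averaged left 99.

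Apcmin small intestinal tumours (n = 2) against wt small intestinal mucosa (n = 1) showed falls in gastric and pancreatic genes and no single Wnt target past the threshold. Muc5ac was at least 72.9-fold lower, and Gkn2 (-7.12 ± 0.68), Tff1 (-4.81 ± 0.70) and the claudin Cldn18 (-3.57 ± 0.52) fell (adjusted p from 1.08e-05 to 0.0336). The gastric and Brunner gland list median was 3.38 log2 lower than in the lone wt sample. Of the exocrine pancreas genes, 2 of 8 fell and 0 rose (4 and 0 adjusted over the list alone, camera adjusted p = 1.47e-37). Among them were Ctrb1 (-3.45 ± 0.23) and Ctrl (-3.22 ± 0.31). Psca (-5.63 ± 0.53) fell and Gsdma2, a gasdermin, was at least 17.0-fold lower. Of the Wnt target genes, 0 of 23 rose and 0 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.0121). The list as a whole shifted toward higher values, with Axin2 at 1.00 ± 0.26 and Lgr5 at 0.59 ± 0.62 (adjusted p = 0.806 and 1.00). In the 2 tumour samples Notum read 5.91 and 8.88, Wif1 5.24 and 8.09 and Prox1 4.85 and 8.10 log2 intensity, against 5.40, 5.04 and 4.79 in wt mucosa. No gene was called higher, and of the rises the kinase Dyrk3 (2.17 ± 0.41, adjusted p = 0.250), the channel-like Ttyh3 (1.07 ± 0.22, 0.292) and the zinc finger protein Zscan21 (0.86 ± 0.19, 0.471) came closest. Of the tuft cell genes, 0 of 12 rose and 0 fell (0 and 1 adjusted over the list alone, camera adjusted p = 4.32e-05), a shift toward lower values. Smooth muscle markers did not pass singly: 0 of 17 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.000353, adjusted p = 0.244 with an estimated correlation). Limma called 10 of the 11230 genes on the 14 arrays, 0 higher and 10 lower. With the 16 arrays of the planned fit, limma called 0, and 29 genes had an unadjusted p under 0.05. Without single arrays the count ran from 7 without wt colon replicate 1 to 91 without Apcmin small intestinal replicate 1, over 1.5 times off in 2 of 15 runs.

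LIN28B/Apcmin (n = 3) against wt colon mucosa (n = 2) gave the most calls. Wnt target genes rose: 20 of 23 rose and 1 fell (20 and 2 adjusted over the list alone, camera adjusted p = 6.51e-12). Among them were Prox1 (6.16 ± 0.69), Notum (6.03 ± 0.67), Axin2 (2.98 ± 0.19) and Lgr5 (1.55 ± 0.45). Colonocyte genes fell: 20 of 23 fell and 0 rose (22 and 0 adjusted over the list alone, camera adjusted p = 3.33e-33). They included Cyp2c55 (-8.00 ± 0.76) and Mptx1 (-7.22 ± 0.24). Goblet cell genes fell: 1 of 16 rose and 15 fell (1 and 15 adjusted over the list alone, camera adjusted p = 2.43e-11). Members included Clca1 (-6.07 ± 0.58). Of the enteroendocrine genes, 1 of 22 rose and 15 fell (1 and 18 adjusted over the list alone, camera adjusted p = 5.45e-10). These included Insl5 (-4.92 ± 0.47) and Gcg (-5.55 ± 0.44). Of the let-7 targets, 12 of 28 rose and 1 fell (13 and 3 adjusted over the list alone, camera adjusted p = 0.00134). Those called included Arid3a (1.90 ± 0.26) and Igf2bp3 (2.16 ± 0.61). S100a8 (7.13 ± 0.55), Lcn2 (7.08 ± 0.72), Defa20 (7.71 ± 0.49) and Sycn (-7.28 ± 0.44) were among the other largest changes. Smooth muscle markers were lower: 16 of 17 fell and 0 rose (16 and 0 adjusted over the list alone, camera adjusted p = 2.99e-24). Limma called 3378 of the 11230 genes on the 14 arrays, 1671 higher and 1707 lower, where median scaling gave 1176 and 2212. The fit over 16 arrays called 12, 3 higher and 9 lower. Leave-outs took the count from 1331 without wt colon replicate 1 to 4060 without LIN28B/Apcmin small intestinal replicate 2, over 1.5 times off in 3 of 16 runs.

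LIN28B/Apcmin small intestinal tumours (n = 2) against wt small intestinal mucosa (n = 1) had Gbx2 at least 31.5-fold and Prox1 at least 24.5-fold higher. Of the Wnt target genes, 4 of 23 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00320), with rises in Notum (5.16 ± 0.93), Lgr5 (2.40 ± 0.62) and Axin2 (1.71 ± 0.26). Paneth cell genes fell, Ang4 (-7.17 ± 1.15) among them: 4 of 10 fell and 0 rose (7 and 0 adjusted over the list alone, camera adjusted p = 5.83e-07). Tuft cell genes fell, Alox5ap (-3.33 ± 0.30) among them: 6 of 12 fell and 0 rose (7 and 0 adjusted over the list alone, camera adjusted p = 7.41e-08). Targets of let-7 rose, Plagl2 (1.28 ± 0.25) among them: 2 of 28 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 3.02e-05). Gastric genes fell, Gkn2 (-6.83 ± 0.68) among them: 4 of 14 fell and 0 rose (9 and 0 adjusted over the list alone, camera adjusted p = 1.36e-11). Smooth muscle markers were lower, Des (-3.26 ± 0.58) among them: 8 of 17 fell and 0 rose (12 and 0 adjusted over the list alone, camera adjusted p = 1.36e-11). Limma called 624 of the 11230 genes on the 14 arrays, 289 higher and 335 lower, where median scaling gave 167 and 368. The limma fit planned over all 16 arrays called 0, with 440 genes at an unadjusted p under 0.05. Leaving out an array or number took it from 124 without LIN28B/Apcmin small intestinal replicate 2 to 1561 without LIN28B/Apcmin small intestinal replicate 1, over 1.5 times off in 12 of 15 runs.

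Adding Apcmin to LIN28B in the small intestine (n = 2 and 2, 3 against 8 months) went with higher levels of the enterocyte genes Cyp3a11 (5.51 ± 0.81), Apoc3 (3.14 ± 0.59) and Apoa4 (2.99 ± 0.52). LIN28B replicate 1 (D) read 8.15 and 10.85 log2 intensity for Cyp3a11 and Apoc3, and replicate 2 (Jej) 4.46 and 8.13. Without replicate 2 the differences were 3.67 (adjusted p = 0.00770), 1.78 (adjusted p = 0.0463) and, for Apoa4, 1.83 (adjusted p = 0.0532). Of the enterocyte list, 4 of 28 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 6.28e-11, adjusted p = 0.115 with an estimated correlation). The transporters Slc13a2 (4.84 ± 0.63) and Slc47a1 (4.77 ± 0.47) and Axin2 (1.39 ± 0.21) rose, and Igf2bp3 was at least 8.43-fold higher. The interferon-induced Ifit2 (-3.72 ± 0.66), the cytokine Il1b (-2.76 ± 0.40) and the chaperone Hsph1 (-2.86 ± 0.22) fell. Of the interferon response genes, 1 of 22 fell and 0 rose (14 and 0 adjusted over the list alone, camera adjusted p = 4.84e-12, adjusted p = 0.115 with an estimated correlation). The intestinal stem cell list had a median of -0.076 and a mean of 0.26, with a test toward higher values: 2 of 19 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.0314, adjusted p = 0.0625 with an estimated correlation). The immediate early list had a median of 0.15 and a mean of -0.39, with a test toward lower values: 2 of 15 fell and 0 rose (3 and 0 adjusted over the list alone, camera adjusted p = 0.0215, adjusted p = 0.174 with an estimated correlation). Limma called 136 of the 11230 genes on the 14 arrays, 70 higher and 66 lower, where median scaling gave 83 and 370. The limma fit planned over all 16 arrays called 0, with 33 genes at an unadjusted p under 0.05. The small intestine fitted alone and the 2 groups fitted alone both had 0 called by limma (1241 and 1343 genes at an unadjusted p under 0.05). The leave-outs ran from 21 without LIN28B small intestinal replicate 2 to 802 without LIN28B/Apcmin small intestinal replicate 1, over 1.5 times off in 15 of 16 runs, and 3 of the 10 called genes named kept their call whichever array was left out.

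Whether the LIN28B difference itself differed between organs was tested as an interaction, colon minus small intestine. It was higher in the colon for the defensin Defa39 (5.92 ± 0.57, 0.13 ± 0.38 in colon, -5.79 ± 0.43 in small intestine), the nucleoside transporter Slc28a1 (4.37 ± 0.60, 0.17 ± 0.40 in colon, -4.20 ± 0.45 in small intestine) and the aquaglyceroporin Aqp7 (4.08 ± 0.47, 0.011 ± 0.31 in colon, -4.07 ± 0.35 in small intestine). It was lower for Mptx1 (-4.06 ± 0.34, -4.39 ± 0.24 in colon, -0.32 ± 0.24 in small intestine), Atp4a (-4.15 ± 0.53, -0.27 ± 0.35 in colon, 3.88 ± 0.39 in small intestine), the hepcidin Hamp2 (-4.29 ± 0.60, -3.00 ± 0.42 in colon, 1.30 ± 0.43 in small intestine) and Lgr5 (-3.69 ± 0.68, -1.89 ± 0.45 in colon, 1.80 ± 0.51 in small intestine), with adjusted p from 0.00262 to 0.0444. Aqp7 was undetected on all colon tumour arrays, Slc28a1 on both Apcmin colon arrays and Atp4a on both Apcmin small intestinal arrays, so that these 3 differences are limited by the floor. Of the interferon response genes, 2 of 22 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 1.17e-08, adjusted p = 0.312 with an estimated correlation). Members included Oasl1 (3.19 ± 0.55), an interferon-induced gene. The colonocyte list had a median of 0.057 and a mean of -0.28, with a test toward lower values, and Aqp8 (-3.09 ± 0.52) fell: 3 of 23 fell and 0 rose (4 and 0 adjusted over the list alone, camera adjusted p = 0.0226, adjusted p = 0.439 with an estimated correlation). Of the let-7 targets, 0 of 28 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.664). Limma called 60 of the 11230 genes on the 14 arrays, 31 higher and 29 lower, where median scaling gave 37 and 90. With the 16 arrays of the planned fit, limma called 0, and 75 genes had an unadjusted p under 0.05. Counts without single arrays or numbers ran from 4 without Apcmin colon replicate 2 to 655 without Apcmin small intestinal replicate 2, over 1.5 times off in 15 of 16 runs, and 2 of the 10 called genes named kept their call whichever array was left out. The groups compared, fitted alone, had 2 called.

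Normal colon mucosa (n = 2) was set against normal small intestinal mucosa (n = 1) as an organ difference. Small intestinal enterocyte genes were lower: 1 of 28 rose and 19 fell (1 and 24 adjusted over the list alone, camera adjusted p = 1.49e-55). The apolipoproteins Apoa1 and Apoa4 were at least 882-fold and 706-fold lower, and the disaccharidase Sis (-7.86 ± 0.61) fell. Paneth cell genes were lower, Defa20 (-9.78 ± 0.69) among them: 6 of 10 fell and 0 rose (7 and 0 adjusted over the list alone, camera adjusted p = 3.71e-11). Colonocyte genes were higher: 9 of 23 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 1.75e-15). Mptx1 (5.36 ± 0.30) rose, Tgm3 was at least 18.2-fold and the colonic hormone Insl5 at least 49.5-fold higher. Gastric genes were lower: 10 of 14 fell and 0 rose (11 and 0 adjusted over the list alone, camera adjusted p = 5.40e-30). Tff1 was at least 933-fold and Gkn2 at least 583-fold lower. Limma called 666 of the 11230 genes on the 14 arrays, 333 higher and 333 lower. The fit over 16 arrays called 231, 147 higher and 84 lower. Left-out arrays and numbers moved it from 328 without wt colon replicate 1 to 870 without the arrays of title number 2135, over 1.5 times off in 2 of 15 runs.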

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

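The tests on interferon genes, on gastric genes and on the precision of the lone wt array were chosen after the results were seen, while those on normal mucosa and on splits of the samples were written before their own values were seen. In LIN28B/Apcmin colon tumours, 12% of probes were detected on replicate 4, apart from the other 3 arrays of its group by 0.830 of the range of all 4, where a gap this large arises in about 1 in 20 groups of 4. The difference between LIN28B/Apcmin and Apcmin tumours itself differed between colon and small intestine for 60 genes by an interaction test. These included Defa39 (5.92), Slc28a1 (4.37), Aqp7 (4.08), Lgr5 (-3.69), Mptx1 (-4.06), Atp4a (-4.15) and Hamp2 (-4.29), as log2 differences of colon minus small intestine. Those of Aqp7, Slc28a1 and Atp4a are limited by the floor, as they were undetected in the groups named above. Of 963 probes without a gene name, used in no comparison of genes, 50 were called between LIN28B/Apcmin and Apcmin tumours of both organs, 25 higher and 25 lower. The largest changes were in ILMN_2818484 (-2.88), ILMN_1238736 (-2.81), ILMN_2906728 (2.70) and ILMN_2974720 (2.50), named after their values were seen.

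The comparison of LIN28B/Apcmin with Apcmin tumours of both organs called 772 genes on the 14 arrays, and 1 of the 60 splits of these 9 arrays within organ, the real split, gave as many. The highest other split gave 252. As 3 of the arrays share a title number, the splits do not exclude chance differences between title numbers. With the 16 arrays planned, 90 of 90 splits gave at least the 0 of the real one. The highest other gave 170, and the 6 splits that called any gene set LIN28B/Apcmin colon replicates 3 and 4, those of lost signal, apart from replicates 1 and 2.

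Interferon genes were higher in LIN28B/Apcmin than Apcmin colon tumours (list median 1.85), and some lower in Apcmin than wt. A joint rise of immune cells is argued against, though not of 1 type. The 60 T cell, B and plasma cell, MHC class II and myeloid members had a median of -0.069 (quartiles -0.33, 0.18). A trait of 1 animal stays open, as all 3 arrays used share title number 2135. Left-out replicate 4, of another number, had 12 readable interferon probes of 11 genes. Their median lay 2.18 above Apcmin (SD of random sets 0.23) and 1.48 above wt colon (12 of 12 higher). Reading may favour high ones, as 34.3% of 35 such probes were readable against 19.5% of 3518 bright probes. A LIN28B effect in either organ also stays open, as adjusted p = 0.933 for the list in the small intestine (estimated correlation) does not exclude it.

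Gastric and Brunner gland genes were lower in LIN28B, Apcmin and LIN28B/Apcmin small intestinal tumours than in the wt mucosa sample, with list medians that fell by 3.02, 3.38 and 4.15. A candidate explanation is sampling at different places along the small intestine, although the titles gave D for all of these samples except LIN28B replicate 2 (Jej). The test asked for spread within a group, and the 2 Apcmin tumours, both D, differed by 2.75 in the list median, against 0.24 between D and Jej in the LIN28B group and 0.90 in LIN28B/Apcmin, so that the site titled does not follow the spread. A loss of these genes in tumours cannot be told apart from it, since the highest tumour sample lay 2.00 under the only wt sample.

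Against wt mucosa, Apcmin small intestinal tumours gave 10 called genes, where LIN28B and LIN28B/Apcmin tumours gave 419 and 624 against the same array. Too little precision from the lone wt array stays open, since 419 and 624 rest on a spread shared with the colon groups, and fits of the small intestine alone called 3, 12 and 7 genes in the same order. Normal mucosa within Apcmin replicate 1 is a candidate explanation, since without that array the count was 91, as the test had set out, and Notum read 5.91 there, 8.88 in replicate 2 and 5.40 in wt mucosa. Without replicate 2 the count was 39, so that part of the rise may come from the unlike pair itself. That Apcmin tumours at this site differ less from mucosa was not tested.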

How the results depend on the processing

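The alternatives were written before the data were examined, except the restriction to 14 arrays and every alternative run on those 14, which were chosen after the signal of each array was seen, and the 14 with signals under 25 kept, chosen after the results. Comparisons are named by their groups, with SI for small intestine, both organs for LIN28B/Apcmin against Apcmin in both, and colon minus SI for the interaction. With 14 arrays in place of 16 the counts were 1708 (Apcmin vs wt colon), 3378 (LIN28B/Apcmin vs wt colon), 187 (LIN28B/Apcmin vs Apcmin colon), 419 (LIN28B vs wt SI), 10 (Apcmin vs wt SI), 624 (LIN28B/Apcmin vs wt SI), 587 (LIN28B/Apcmin vs Apcmin SI), 414 (LIN28B vs Apcmin SI), 136 (LIN28B/Apcmin vs LIN28B SI), 772 (both organs), 60 (colon minus SI) and 666 (wt colon vs wt SI). The 14 arrays with signals under 25 kept, in place of missing, gave 1377 (Apcmin vs wt colon), 3464 (LIN28B/Apcmin vs wt colon), 190 (LIN28B/Apcmin vs Apcmin colon), 314 (LIN28B vs wt SI), 8 (Apcmin vs wt SI), 402 (LIN28B/Apcmin vs wt SI), 333 (LIN28B/Apcmin vs Apcmin SI), 320 (LIN28B vs Apcmin SI), 94 (LIN28B/Apcmin vs LIN28B SI), 638 (both organs), 35 (colon minus SI) and 479 (wt colon vs wt SI), so that leaving out the 2 arrays of almost no signal moved the counts without the other choice, which itself moved 3 of them over 1.5 times. Only counts that moved over 1.5 times are given next. Cyclic loess gave, over 16 arrays, 705 (Apcmin vs wt colon), 1219 (LIN28B/Apcmin vs wt colon), 1 (LIN28B vs wt SI), 1 (LIN28B/Apcmin vs wt SI), 4 (LIN28B/Apcmin vs Apcmin SI), 2 (LIN28B vs Apcmin SI), 22 (LIN28B/Apcmin vs LIN28B SI), 5 (both organs) and 392 (wt colon vs wt SI). Median scaling gave, over 16 arrays, 62 (Apcmin vs wt colon) and 172 (LIN28B/Apcmin vs wt colon). The series matrix values gave, over 16 arrays, 0 (LIN28B/Apcmin vs wt colon) and 78 (wt colon vs wt SI). No block for the title number gave, over 16 arrays, 85 (LIN28B/Apcmin vs wt colon) and 40 (wt colon vs wt SI). Averaging arrays that share a title number gave, over 16 arrays, 2 (LIN28B/Apcmin vs wt colon) and 15 (wt colon vs wt SI). The replicate number as a block gave, over 16 arrays, 44 (Apcmin vs wt colon), 187 (LIN28B/Apcmin vs wt colon) and 102 (wt colon vs wt SI). Fitting only the groups compared gave, over 16 arrays, 3841 (Apcmin vs wt colon), 0 (LIN28B/Apcmin vs wt colon), 1 (LIN28B/Apcmin vs LIN28B SI) and 0 (wt colon vs wt SI). Fitting only the organ compared gave, over 16 arrays, 0 (LIN28B/Apcmin vs wt colon). Array weights gave, over 16 arrays, 4002 (Apcmin vs wt colon), 3641 (LIN28B/Apcmin vs wt colon), 344 (LIN28B/Apcmin vs Apcmin colon), 300 (LIN28B/Apcmin vs Apcmin SI), 412 (LIN28B vs Apcmin SI), 142 (LIN28B/Apcmin vs LIN28B SI), 672 (both organs), 81 (colon minus SI) and 0 (wt colon vs wt SI). An adjusted p under 0.01 gave, over 16 arrays, 2 (LIN28B/Apcmin vs wt colon) and 87 (wt colon vs wt SI). On the 14 arrays, an adjusted p under 0.01 left 737 (Apcmin vs wt colon), 1796 (LIN28B/Apcmin vs wt colon), 19 (LIN28B/Apcmin vs Apcmin colon), 77 (LIN28B vs wt SI), 6 (Apcmin vs wt SI), 63 (LIN28B/Apcmin vs wt SI), 63 (LIN28B/Apcmin vs Apcmin SI), 79 (LIN28B vs Apcmin SI), 25 (LIN28B/Apcmin vs LIN28B SI), 132 (both organs), 14 (colon minus SI) and 330 (wt colon vs wt SI), and the added 2-fold minimum 1838 (LIN28B/Apcmin vs wt colon) and 284 (both organs), each a stricter threshold. Median scaling of the 14 gave 376 (LIN28B/Apcmin vs Apcmin colon), 754 (LIN28B vs wt SI), 385 (LIN28B/Apcmin vs Apcmin SI), 1264 (LIN28B vs Apcmin SI), 453 (LIN28B/Apcmin vs LIN28B SI) and 127 (colon minus SI). No detection filter gave 28 (Apcmin vs wt SI) and 33 (colon minus SI) and the strict detection filter 28 (Apcmin vs wt SI). Averaging title numbers, which leaves fewer samples, gave 1485 (LIN28B/Apcmin vs wt colon), 27 (LIN28B/Apcmin vs Apcmin colon), 99 (LIN28B vs wt SI), 331 (LIN28B/Apcmin vs wt SI), 254 (LIN28B/Apcmin vs Apcmin SI), 63 (LIN28B vs Apcmin SI), 18 (LIN28B/Apcmin vs LIN28B SI), 142 (both organs) and 9 (colon minus SI). The replicate block gave 103 (LIN28B/Apcmin vs Apcmin colon), 750 (LIN28B vs wt SI), 1392 (LIN28B/Apcmin vs wt SI) and 1040 (LIN28B/Apcmin vs Apcmin SI), although the replicate number pairs arrays weakly, since correlations within 2 of 10 group pairs passed 0.1 (range -0.0335 to 0.356). Fits of only the groups compared, with fewer arrays, gave 3756 (Apcmin vs wt colon), 659 (LIN28B/Apcmin vs Apcmin colon), 47 (LIN28B vs wt SI), 0 (Apcmin vs wt SI), 4 (LIN28B/Apcmin vs wt SI), 0 (LIN28B/Apcmin vs Apcmin SI), 0 (LIN28B vs Apcmin SI), 0 (LIN28B/Apcmin vs LIN28B SI), 221 (both organs), 2 (colon minus SI) and 2189 (wt colon vs wt SI), and fits of only the organ 2701 (Apcmin vs wt colon), 1081 (LIN28B/Apcmin vs Apcmin colon), 12 (LIN28B vs wt SI), 3 (Apcmin vs wt SI), 7 (LIN28B/Apcmin vs wt SI), 12 (LIN28B/Apcmin vs Apcmin SI), 0 (LIN28B vs Apcmin SI) and 0 (LIN28B/Apcmin vs LIN28B SI). Array weights on the 14 gave 3950 (Apcmin vs wt colon), 76 (LIN28B/Apcmin vs Apcmin SI), 175 (LIN28B vs Apcmin SI), 71 (LIN28B/Apcmin vs LIN28B SI), 406 (both organs), 19 (colon minus SI) and 1132 (wt colon vs wt SI). Leaving out 1 array or title number over 16 arrays gave counts of 0 to 74 (Apcmin vs wt colon, highest without LIN28B/Apcmin colon replicate 4), 0 to 6644 (LIN28B/Apcmin vs wt colon, highest without the arrays of title number 2135), 0 to 6691 (LIN28B/Apcmin vs Apcmin colon, highest without the arrays of title number 2135), 0 to 1606 (LIN28B vs wt SI, highest without wt SI replicate 2), 0 to 3134 (Apcmin vs wt SI, highest without wt SI replicate 2), 0 to 3245 (LIN28B/Apcmin vs wt SI, highest without wt SI replicate 2), 0 to 4272 (both organs, highest without the arrays of title number 2135), 0 to 4632 (colon minus SI, highest without the arrays of title number 2135) and 90 to 7890 (wt colon vs wt SI, highest without wt colon replicate 2), and 0 to 0 by limma in the other 3 (71, 48 and 33 genes at an unadjusted p under 0.05 with all arrays). On the 14 arrays these ranges were 573 to 2162 (Apcmin vs wt colon), 1331 to 4060 (LIN28B/Apcmin vs wt colon), 5 to 479 (LIN28B/Apcmin vs Apcmin colon), 80 to 1197 (LIN28B vs wt SI), 7 to 91 (Apcmin vs wt SI), 124 to 1561 (LIN28B/Apcmin vs wt SI), 52 to 1542 (LIN28B/Apcmin vs Apcmin SI), 53 to 1295 (LIN28B vs Apcmin SI), 21 to 802 (LIN28B/Apcmin vs LIN28B SI), 103 to 1537 (both organs), 4 to 655 (colon minus SI) and 328 to 870 (wt colon vs wt SI), and a lone sample left in a group is assumed to vary like the others. Without Apcmin SI replicate 1 the counts that moved were 447 (LIN28B/Apcmin vs Apcmin colon), 1172 (LIN28B vs wt SI), 91 (Apcmin vs wt SI), 1353 (LIN28B/Apcmin vs wt SI), 234 (LIN28B/Apcmin vs Apcmin SI), 361 (LIN28B/Apcmin vs LIN28B SI) and 128 (colon minus SI), and without LIN28B/Apcmin colon replicate 3, read in part, 992 (LIN28B vs wt SI), 957 (LIN28B/Apcmin vs wt SI), 917 (LIN28B vs Apcmin SI), 388 (LIN28B/Apcmin vs LIN28B SI) and 91 (colon minus SI). Of the list shifts, 183 passed on the 14 arrays, 112 to 190 with an array left out, 74 with an estimated correlation and 103 with fry, against 107 to 170, 37 and 9 over 16 arrays. The 265 gene values named kept call and direction or stayed uncalled in 6937 of 8196 runs on the 14 arrays. They lost the call in 1236, gained it in 23 and turned in 0. Over 16 arrays 23 kept both or stayed uncalled, 238 lost the call and 4 turned. These 4 were Cdc34 (-1.18) and E2f6 (-0.98) in LIN28B/Apcmin vs Apcmin colon and Axin2 (-0.43) and Cdc34 (-0.055) in both organs. Their adjusted p ran from 0.622 to 0.995. The lists that passed kept call and direction in 3216 of 3589 runs, and 3 medians turned in Apcmin vs wt SI without Apcmin SI replicate 2, those of the proliferation (-0.21 to 0.66 over the arrays left out), enteroendocrine (-0.62 to 0.27) and ribosome biogenesis (-0.036 to 0.53) genes. Other than for a stricter threshold, fewer samples or the 2 arrays left out, the cause of a move was not tested. No slide is given to run as a block. Signal over background limits genes near the floor, where undetected groups allow only a bound.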

Other observations

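The lists in this part were written before the data were examined, and their values come from the 14 arrays, chosen after their signals were seen. Ribosome biogenesis genes shifted upward in Apcmin colon tumours against wt: 7 of 20 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.000496, adjusted p = 0.437 with an estimated correlation). In LIN28B small intestinal tumours against wt mucosa, 0 of 20 rose and 0 fell (14 and 0 adjusted over the list alone, camera adjusted p = 3.13e-08, adjusted p = 0.143 with an estimated correlation). Of the red blood cell genes, 0 of 5 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 4.11e-07) in Apcmin small intestinal tumours against wt, toward higher values. MHC class II genes fell in LIN28B/Apcmin small intestinal tumours against wt: 5 of 9 fell and 0 rose (7 and 0 adjusted over the list alone, camera adjusted p = 1.04e-07, adjusted p = 0.107 with an estimated correlation). Fibroblast and matrix genes were lower in LIN28B/Apcmin than in LIN28B small intestinal tumours: 2 of 21 fell and 0 rose (11 and 0 adjusted over the list alone, camera adjusted p = 2.92e-08, adjusted p = 0.115 with an estimated correlation). Of the T cell genes, 0 of 15 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.00989, adjusted p = 0.399 with an estimated correlation) in LIN28B against Apcmin small intestinal tumours, toward lower values. Of the adipocyte genes, 1 of 7 fell and 0 rose (2 and 0 adjusted over the list alone, camera adjusted p = 0.000820, adjusted p = 0.0846 with an estimated correlation) in the same comparison, where Adipoq read 4.59 and 9.73 log2 intensity on the 2 Apcmin arrays, Car3 4.33 and 8.93 and Lep 5.17 and 7.53. Without Apcmin replicate 2 the list shift did not pass (adjusted p = 0.156).

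Of the B and plasma cell genes, 3 of 14 fell and 0 rose (4 and 0 adjusted over the list alone, camera adjusted p = 0.00191, adjusted p = 0.324 with an estimated correlation) in LIN28B/Apcmin against Apcmin tumours of both organs. Of the glycolysis genes, 0 of 15 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.263) there, with a median of 0.11. Endothelial genes shifted upward in Apcmin colon tumours against wt: 3 of 17 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0199, adjusted p = 0.437 with an estimated correlation). Of the Notch and secretory fate genes, 1 of 12 rose and 0 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.213) in that comparison. The regenerating islet-derived and antimicrobial list had a median of -0.62 and a mean of 0.19 there, with a test toward higher values: 3 of 13 rose and 2 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.914). Of the imprinted growth genes, 0 of 10 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.0514) in LIN28B/Apcmin against Apcmin colon tumours.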
